A study of Arabidopsis thaliana with 30 samples.

How the data were processed

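RNA was sequenced from roots of 7-day-old Arabidopsis seedlings after 4 h of treatment, in 30 libraries made with a stranded mRNA kit, per the labels. The groups were taken from the titles and characteristics of the samples: 10 groups of 3 in an RGF1 set (6 libraries), an RGI1 set (12) and an RGI5 set (12). The columns of the wild type of the RGI1 set were matched to their titles by elimination, since the names differ slightly. All columns were used. Mock samples of the RGI1 and RGI5 sets were named after the solvent in the file.

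The authors deposited transcript abundances as TPM, 1 value per transcript model and library. That unit was read from the values, which sum to the same round total in each column and are not whole numbers. The processing notes of the authors name Salmon and DESeq2 without a version or a role, and the transcript index, genome build and annotation are not given in the sources used here. TPM keep no depth, so counting error could not be computed. The file held 40812 transcripts, of which 5395 were at 0 in all libraries. TPM were summed over transcripts to 32753 genes, and 32048 of these were matched by identifier to a TAIR10.1 annotation, which was used for names alone. Engineered and native copies of RGI1, RGI5 and BAK1 were not separated, and reads of near-identical paralogs can be split between copies.

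Gene values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior. The planned edgeR test was not used, since it needs counts, and the fallback written beforehand for normalized values was used. A gene was tested in a fit when it reached 1 TPM in at least 3 of its libraries. Each set had its own fit of group means. The 4 comparisons between sets (the differences between line responses, RGF1 response and wild-type responses) used a fit of all 30 libraries. There were 13 comparisons: RGF1 against mock, rapamycin against mock in each wild type and each line, the difference between each line and its wild type in that response, each line against its wild type under mock, and the 4 between sets. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was a call. Without any change, an unadjusted p under 0.05 would be expected for 964 genes (RGF1) to 1006 genes (comparisons between sets). Fold changes are differences of mean log2(TPM + 1), which understate the changes of weakly expressed genes. Group levels are given as mean TPM ± SD.

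Groups, comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from median-ratio scaling. The rule named, for each comparison, up to 8 called genes with the highest and up to 8 with the lowest log2 fold change, among those with a mean of at least 1 TPM and group values that did not overlap, an outcome that chance gives in 10% of genes for 3 against 3. It also named up to 4 called genes with the smallest p in each list with at least 2 calls, and RGI1, RGI5, BAK1, PLT1, PLT2, RITF1, LBD16, LBD18, LBD29, GATA23 and PUCHI in the responses to RGF1 and in both lines. Genes lowest in each order were left out where space required.

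The 19 lists held 328 genes: RGF peptides, RGI receptors and co-receptors; root stem cell niche and PLETHORA; lateral root initiation and emergence; primary auxin response; pattern-triggered immunity; class III peroxidases and NADPH oxidases; Casparian strip and suberin; S phase; G2 and mitosis; root hair; jasmonate; ethylene; brassinosteroid; expansins and xyloglucan endotransglucosylases; iron deficiency; hypoxia; heat shock; circadian clock; and photosynthesis as a marker of green shoot tissue. Each was tested with camera in limma with a preset correlation between genes of 0.01 and with a correlation estimated from the data, and with fry, adjusted over the lists of a comparison. Gene families with at least 8 tested members, read from the product names or from the stem of the gene symbol (XTH or WRKY, for example), were tested for an excess of calls with a one-sided hypergeometric (Fisher's exact) test against all genes tested. Overlaps of calls were tested with the same test among genes tested in both comparisons.

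The alternatives were quantile normalization, no filter on low values, a mean of at least 5 TPM, pseudocounts of 0.1 and 5, the replicate number as a block, an absolute log2 fold change of at least 1, all 30 libraries in a single fit, and each library left out in turn. Median-ratio scaling was added after the data were seen. Calls were recounted after other splits of the same libraries, 10 for 3 against 3 and 100 for differences of responses. On simulated data with 200 changed genes the tests called 189 genes with 15 false calls for RGF1, and 185 with 7 false calls for the RGI5 line. The changed genes had a mean of about 5 TPM or more and log2 changes of 0.5, 1 or 2. Recovery of weaker genes, or of small changes without large ones beside them, was not measured. At a log2 change of 0.5, 64.2% of changed genes were recovered for RGF1, 88.1% for the RGI1 line, 70.1% for the RGI5 line, and 61.2% and 23.9% for the differences between the RGI1 line or the RGI5 line and wild type. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.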

Results

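Transcript abundance was measured by RNA-seq in roots of 7-day-old Arabidopsis thaliana seedlings after 4 h of treatment, in 30 libraries that fell into 10 groups of 3. RGF1 is a secreted root peptide, the RGI proteins are the receptor kinases that perceive it. BAK1 is a kinase that acts as their co-receptor. The RiD-RGI1/BAK1 and RiD-RGI5/BAK1 lines (called the RGI1 line and the RGI5 line here) carry engineered RGI1 or RGI5 together with engineered BAK1. Rapamycin, a small molecule, is used to bring both partners together without the peptide. The RGF1 set held wild type (Col-0) with mock treatment or 100 nM RGF1. The RGI1 set held wild type and the RGI1 line, each with mock treatment or 1 µM rapamycin. The RGI5 set held wild type and the RGI5 line, each with mock treatment or 100 nM rapamycin. Each set had its own wild-type mock group. The values were TPM, a relative unit that sums to the same total in each library, which keep no record of read depth, so the depth of each library is unknown. Between 18999 and 19331 genes reached 1 TPM in a library. The non-coding RNA AT1G15405 alone took between 3.95% and 11.9% of a library. The labels do not say whether replicates came from separate batches of plants, so p-values measure the spread between these samples, which may be technical.

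The engineered receptors were read first, as a check of the labels. In mock-treated roots RGI1 (AT3G24240) stood at 204.2 ± 4.7 TPM (mean ± SD, n = 3) in the RGI1 line and at 31.7 ± 1.5 TPM in its wild type (log2 fold change 2.65, SE 0.05, limma adjusted p = 3.39e-11). RGI5 (AT1G34110) stood at 47.0 ± 1.5 TPM in the RGI5 line and at 2.9 ± 0.52 TPM in its wild type (3.65, SE 0.10, adjusted p = 1.83e-09). BAK1 (AT4G33430) was higher in both lines, at 183.1 ± 2.7 against 53.4 ± 0.93 TPM in the RGI1 line (1.76, SE 0.04, adjusted p = 1.33e-10) and at 105.2 ± 7.8 against 54.3 ± 3.1 TPM in the RGI5 line (0.94, SE 0.07, adjusted p = 4.17e-05). Reads of the engineered and the native copies count to the same gene, so these levels are sums. Rapamycin left no called change in the engineered receptors: RGI1 differed by 0.16 in the RGI1 line (adjusted p = 0.151) and RGI5 by 0.07 in the RGI5 line (adjusted p = 0.837).

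**Figure D1:**
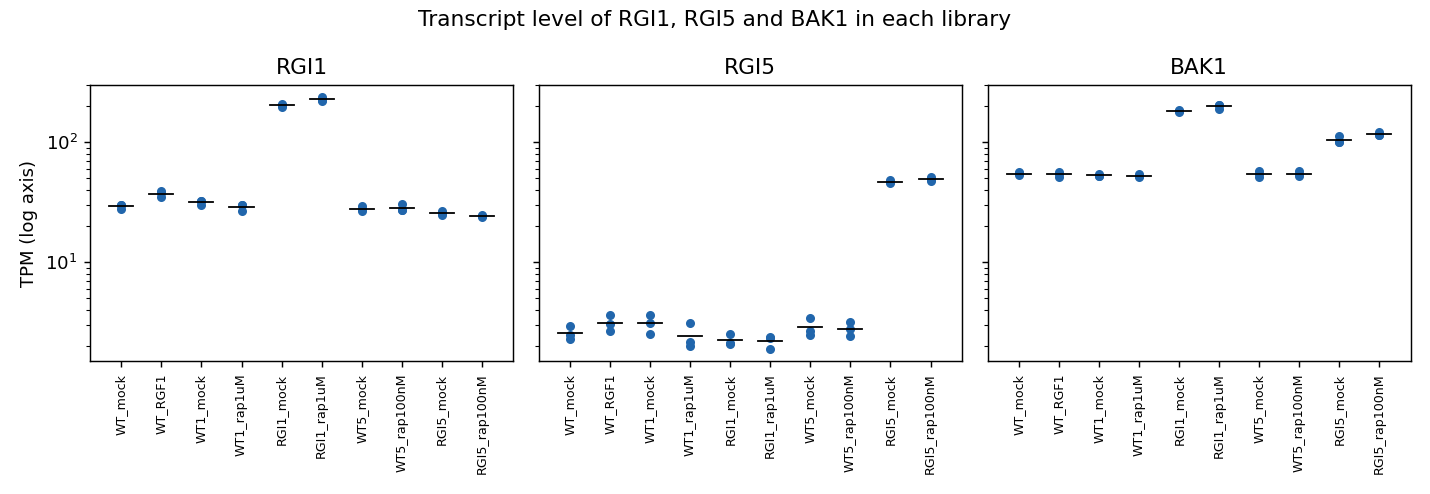
Levels of RGI1, RGI5 and BAK1 (TPM, log axis) in each of the 30 libraries, by group. Points are libraries and bars are group means; RGI1 and BAK1 stand apart in the 6 RGI1-line libraries, and RGI5 and BAK1 in the 6 RGI5-line libraries.

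The RGF1 set asked which genes answered the peptide in wild-type roots within 4 h. PUCHI (AT5G18560), a transcription factor of early lateral root development, rose from 1.48 ± 0.552 to 5.07 ± 0.239 TPM (log2 fold change 1.32, SE 0.17, adjusted p = 0.0329, n = 3 per group). WRKY30 (AT5G24110), a defence-related transcription factor, rose from 0.388 ± 0.121 to 3.76 ± 1.6 TPM (1.73, SE 0.23, adjusted p = 0.0329). The chitinase gene AT2G43620 rose from 9.40 ± 1.18 to 23.7 ± 2.33 TPM (1.25, SE 0.11, adjusted p = 0.00834). Among the genes called lower were the expansin EXPA12 (AT3G15370), from 2.80 ± 0.569 to 0.231 ± 0.0443 TPM (-1.62, SE 0.16, adjusted p = 0.0103), the arabinogalactan protein AGP30 (AT2G33790), from 32.2 ± 2.22 to 15.7 ± 2.19 TPM (-1.0, SE 0.10, adjusted p = 0.0103), and the xyloglucan endotransglucosylases XTH5 (AT5G13870) (-0.80, adjusted p = 0.00834), XTH15 (AT4G14130) (-0.76, adjusted p = 0.00834) and XTH17 (AT1G65310) (-0.67, adjusted p = 0.0363). XTH20 (AT5G48070) moved the other way, from 97.2 ± 15.9 to 169.1 ± 3.05 TPM (0.80, adjusted p = 0.0296). The list of expansins and xyloglucan endotransglucosylases as a whole was not called: 9 of 15 members stood above mock, 1 was called higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.475). In the XTH family 3 of the 23 genes tested were lower, where 0.01 were expected by chance (hypergeometric test, adjusted p = 0.00013). After quantile normalization or median-ratio scaling 2 of them were lower and none higher, the calls of XTH17 and XTH20 being lost. The lipase-like gene AT3G27950 (1.37) and the TRAF-like gene AT3G20360 (1.37, adjusted p = 0.0103) also rose, while SWEET12 (AT5G23660), a sugar transporter (-0.88), ST4C (AT1G13430), a sulfotransferase (-0.77), and DGR1 (AT1G80240) (-0.72) fell. Short transcripts of AT5G52355, a serine transfer RNA gene, were listed at 0 in the 3 mock libraries and at 17.8, 8.73 and 9.11 TPM with RGF1. Mock wild type of the RGI1 set had AT5G52355 at 4.52 ± 1.02 TPM, so the level of 0 did not hold in each wild type. AT3G46616 was listed at 0 in mock and at 6.11, 9.45 and 3.16 TPM with RGF1, and AT3G51915 at 0 and at 1.97, 2.01 and 2.06 TPM. The calls of these last 3 genes held in the 3 fits without a library that tested them (highest adjusted p 0.00971, 0.043 and 0.043), the filter leaving them untested in the others. Each of the other calls ended without at least 1 library, EXPA12 and WRKY30 also being untested without some. The highest adjusted p came without RGF1 replicate 2 for PUCHI, XTH17, XTH20, SWEET12 and DGR1 (0.213), AT3G27950 (0.215), ST4C (0.185), AGP30 and AT3G20360 (0.108) and XTH5 (0.0857). It came without RGF1 replicate 4 for AT2G43620 and XTH15 (0.0824) and EXPA12 (0.0894), and without mock replicate 2 for WRKY30 (0.0913).

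Among regulators of root growth that were followed in every set, none other than PUCHI passed the test with RGF1 in the fit of this set. PLT1 (AT3G20840) and PLT2 (AT1G51190), which maintain the root stem cell niche, differed by -0.10 (adjusted p = 0.793) and 0.06 (adjusted p = 0.877). RITF1 (AT2G12646), a transcription factor of the RGF1 pathway, differed by 0.25 (adjusted p = 0.452). The lateral root regulators LBD16 (AT2G42430), LBD18 (AT2G45420), LBD29 (AT3G58190) and GATA23 (AT5G26930) differed by 0.53 (SE 0.12, adjusted p = 0.175), -0.10, -0.13 and -0.33. The result of LBD16 depended on the setting, its lowest limma adjusted p over the alternatives being 0.0135. So did that of the receptor gene RGI1, at 29.3 ± 1.3 TPM in mock and 37.5 ± 2.1 TPM with RGF1 (0.34, adjusted p = 0.15, lowest over the alternatives 0.00394). Of the genes listed before the data were examined, the lateral root list had 1 of 19 members higher (4 adjusted over the list alone), and camera with a preset correlation placed it above other genes (adjusted p = 0.0213). Its median was -0.07. The list of pattern-triggered immunity had 1 of 30 members higher (1 adjusted over the list alone, camera adjusted p = 0.000354). The stem cell list had 0 of 14 called (3 higher adjusted over the list alone, adjusted p = 0.00438) and the G2 and mitosis list 0 of 17 (0 adjusted over the list alone, adjusted p = 0.00076). All 14 root hair genes stood below mock (median -0.16, adjusted p = 0.0118), with none called in limma, where 65.8% of all genes stood below mock (median -0.05). None of these list results held: the adjusted p with an estimated correlation was 0.589 for the lateral root, immunity and root hair lists, 0.644 for the stem cell list and 0.647 for G2 and mitosis. In total 27 of 19274 genes were called in limma (15 higher, 12 lower), against 1956 with an unadjusted p under 0.05 (964 expected by chance). The split was 16 higher and 6 lower under median-ratio scaling and 12 and 5 under quantile normalization, and all 30 libraries in a single fit gave 167 calls (46 higher, 121 lower). Leaving out a single library gave 10 calls (mock replicate 1), 17 (mock replicate 2), 0 (RGF1 replicate 2), 9 (RGF1 replicate 3) and 1 (RGF1 replicate 4). The share of AT1G15405 was 5.24% ± 2.11 in mock and 8.52% ± 1.66 with RGF1.

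Wild-type roots given rapamycin measured the effect of the compound without an engineered receptor. With 1 µM rapamycin limma called 0 of 19634 genes, and 1290 had an unadjusted p under 0.05, where 982 would be expected by chance. The gene with the smallest p was FKF1 (AT1G68050), a light-dependent regulator of flowering time chosen here after its values were seen, at 0.65 (adjusted p = 0.113). Quantile normalization, median-ratio scaling and the fit of all 30 libraries each gave 1 call, as did leaving out rapamycin replicate 1. With 100 nM rapamycin limma called 1 of 19652 genes, and 1481 had an unadjusted p under 0.05 (983 expected by chance). That gene, AT3G58347, was listed at 0 in the 3 rapamycin libraries and at 1.72, 4.1 and 3.2 TPM in mock (adjusted p = 0.0155). Without wild-type mock replicate 4 there were 3 calls, and without any other single library 0. Genes induced by low oxygen stood lower with 100 nM (11 of 11, median -0.49) and higher with 1 µM (9 of 11, median 0.11). In camera the hypoxia list had an adjusted p of 0.000138 at 100 nM and of 0.0168 at 1 µM, and an adjusted p = 0.868 and 0.619 with an estimated correlation. The jasmonate list stood higher with 1 µM (median 0.14, camera adjusted p = 7.94e-05), with an adjusted p = 0.178 with an estimated correlation. With 1 µM the root hair list stood lower in 14 of 14 members (median -0.10, camera adjusted p = 0.0044) and the suberin list in 23 of 26 (median -0.08, adjusted p = 0.00532), both with an adjusted p = 0.374 with an estimated correlation. Camera with the preset correlation called 7 lists at 1 µM in all, the others being peroxidases, heat shock and RGF peptides and receptors, with an adjusted p = 0.619, 0.34 and 0.374 with an estimated correlation. No member of the 4 lists with values here was called, and 0 were called adjusted over the list alone. Between the responses to 1 µM and to 100 nM, limma called 0 of 20113 genes (1508 with an unadjusted p under 0.05, smallest adjusted p 0.166), and 1 when mock replicate 1 or rapamycin replicate 4 of the 1 µM set or rapamycin replicate 3 of the 100 nM set was left out.

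Rapamycin was then given to the RGI1 line to ask which genes answered when engineered RGI1 and BAK1 were brought together. The glutathione transferase genes GSTF6 (AT1G02930) and GSTF7 (AT1G02920) rose from 107.4 ± 14.9 to 350.8 ± 18.7 TPM (log2 fold change 1.71, SE 0.13, adjusted p = 4.08e-05, n = 3 per group) and from 148.3 ± 20.3 to 429.4 ± 21.5 TPM (1.54, SE 0.11, adjusted p = 4.08e-05). CYP71A12 (AT2G30750), a cytochrome P450 of indole-derived defence compounds, rose from 1.66 ± 0.536 to 8.03 ± 1.07 TPM (1.78, SE 0.19, adjusted p = 0.000261), and IGMT2 (AT1G21120), an indole glucosinolate methyltransferase, from 3.21 ± 0.432 to 11.3 ± 1.87 TPM (1.55, SE 0.13, adjusted p = 4.7e-05). The lectin gene AT3G16530 (1.62, adjusted p = 0.000558) and AT3G21352 (1.74, adjusted p = 0.000388) rose as well. Among the genes called lower several encode cell wall proteins: XTH26 (AT4G28850), from 56.1 ± 3.65 to 18.9 ± 4.17 TPM (-1.54, SE 0.14, adjusted p = 8.01e-05), FLA6 (AT2G20520) (-1.41, SE 0.18, adjusted p = 0.000808), PRP3 (AT3G62680) (-1.17, SE 0.14, adjusted p = 0.000536), and the extensin and glycoprotein genes EXT13 (AT5G35190) (-1.45), HRGP1 (AT3G54590) (-1.28) and EXT11 (AT5G49080) (-1.15). AT4G21870, a gene for a small heat shock-like protein (-1.35, adjusted p = 0.000915), and the dioxygenase gene AT2G36690 (-1.34, adjusted p = 4.7e-05) fell too. AT1G76728 was listed at 0 in the 3 mock libraries and at 6.46, 6.78 and 6.44 TPM with rapamycin, and in the wild type of this set it was listed at 0 in 5 libraries and at 3.36 TPM in mock replicate 3. GSTF6 and GSTF7 are close copies of each other, as are the members of the IGMT family, so how their reads were divided is uncertain. EXT13, HRGP1 and EXT11 lost their calls in 5, 4 and 2 of the 6 fits without a library. Their highest adjusted p came without mock replicate 4, at 0.14, 0.0969 and 0.0747.

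In the RGI1 line limma called 796 of 19634 genes (503 higher, 293 lower), and 3063 had an unadjusted p under 0.05. After median-ratio scaling 391 were higher and 360 lower, and after quantile normalization 393 and 363. The count was 530 without mock replicate 1, 422 without mock replicate 3, 402 without mock replicate 4, and 362 in the fit of all 30 libraries. Of the called genes named by the rule, 42 in number, 25 kept their call without each library in turn, 22 under the other alternatives and 20 under both. The log2 fold change of 1 was not among these alternatives, and a gene that they did not test counted as kept. In the fit of all 30 libraries CYP71A12 (adjusted p = 0.139), CYP81F2 (0.48), RSL4 (0.466), WRKY33 (0.299), YLS9 (0.0837) and MOP10 (0.0765) were not called. Regulators of root growth did not pass the test: PLT1 differed by 0.00 (adjusted p = 0.991), PLT2 by -0.01 (0.962), RITF1 by 0.19 (0.41), LBD16 by 0.08 (0.799), LBD18 by -0.02 (0.966), LBD29 by -0.30 (SE 0.08, adjusted p = 0.0728) and GATA23 by 0.53 (SE 0.14, adjusted p = 0.0616). PUCHI lay under the filter on low values and was not tested in this set.

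**Figure D2:**
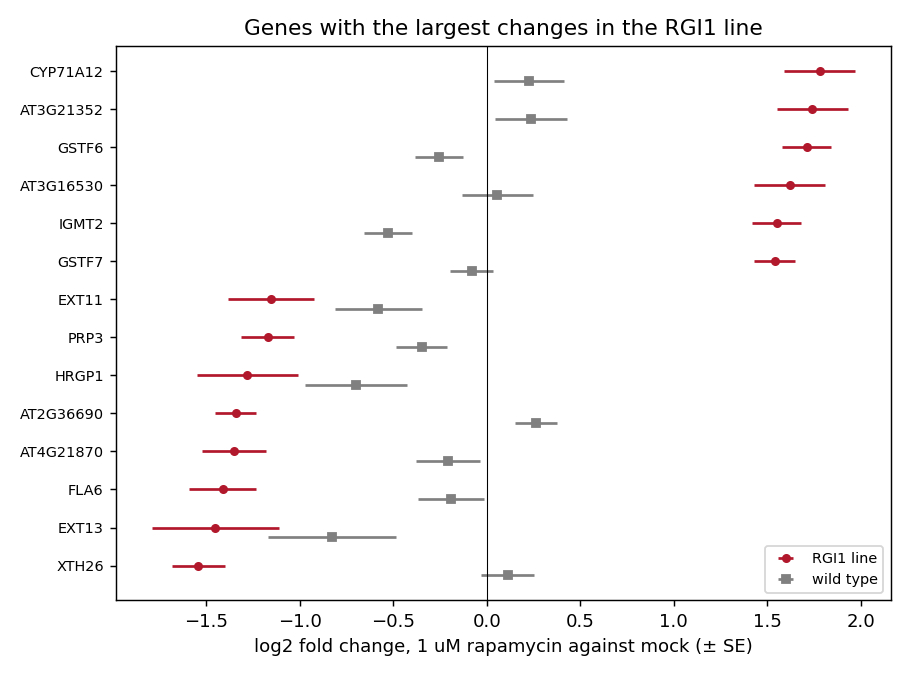
Log2 fold changes with 1 µM rapamycin against mock (x axis) in the RGI1 line (red circles) and its wild type (grey squares), for the 14 called genes with the highest and lowest changes that were not listed at 0 in a whole group. Bars are standard errors, n = 3 per group.

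By lists fixed beforehand, 5 of 29 genes of pattern-triggered immunity rose and none fell (10 higher and 0 lower adjusted over the list alone). They included CYP71A12, CYP81F2 (AT5G57220), a P450 of indole glucosinolate modification (0.80, adjusted p = 0.00194), and YLS9 (AT2G35980), a harpin-responsive gene (0.78, adjusted p = 0.00826). WRKY33 (AT2G38470), a regulator of camalexin synthesis, was also among them (0.39, adjusted p = 0.0153). It lost its call in 4 of the 6 fits without a library (highest adjusted p 0.0642, without mock replicate 3). Camera gave the list an adjusted p of 0.000292 with the preset correlation, and an adjusted p = 0.158 with an estimated correlation. Of 26 Casparian strip and suberin genes 6 rose (8 adjusted over the list alone, adjusted p = 0.000796, and adjusted p = 0.333 with an estimated correlation), including the fatty acyl reductase genes FAR5 (AT3G44550) (0.43, adjusted p = 0.0142, and 0.0525 without rapamycin replicate 3) and FAR4 (AT3G44540) (0.24) and the transporter gene ABCG20 (AT3G53510) (0.32). After median-ratio scaling 2 of the 26 were higher, and after quantile normalization 3. The calls of FAR4, ABCG20 and RWP1 (AT5G41040), a feruloyl transferase of suberin (0.27), were lost in 5, 4 and 4 of the 6 fits without a library. Their highest adjusted p came without mock replicate 4, at 0.145, 0.0816 and 0.128. Of 14 root hair genes 6 fell and 1 rose (7 lower and 3 higher adjusted over the list alone, adjusted p = 0.000293, and adjusted p = 0.333 with an estimated correlation). PRP3, EXPA18 (AT1G62980) (-0.45, adjusted p = 0.00492), MOP10 (AT5G05500) (-0.42, adjusted p = 0.00204) and RSL4 (AT1G27740), a master regulator of hair growth (-0.27, adjusted p = 0.0106, and 0.0542 without mock replicate 3), were among those that fell.

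Of 11 hypoxia genes 3 fell (7 adjusted over the list alone, adjusted p = 1.56e-08, and adjusted p = 0.25 with an estimated correlation), with the transcription factor ERF73 (AT1G72360) at 18.4 ± 0.891 against 36.9 ± 4.77 TPM (-0.96, SE 0.09, adjusted p = 7.9e-05). The other 2 were ADH1 (AT1G77120) for alcohol dehydrogenase (-0.83, adjusted p = 0.0384) and SUS4 (AT3G43190) for sucrose synthase (-0.62, adjusted p = 0.0433). They lost their calls in 5 and 4 of the 6 fits without a library (highest adjusted p 0.137 and 0.169, without mock replicate 4). Of 16 primary auxin response genes 1 fell (5 lower and 1 higher adjusted over the list alone, median -0.26, adjusted p = 2.2e-05, and adjusted p = 0.333 with an estimated correlation). The peroxidase and NADPH oxidase list had 4 members higher and 4 lower of 19 (4 and 7 adjusted over the list alone, adjusted p = 0.0888): PRXCB (AT3G49120) rose (0.67, adjusted p = 0.000563), while PRX1 (AT1G05240) (-0.67, adjusted p = 6.15e-05), PRX44 (AT4G26010) (-0.65, adjusted p = 0.000337) and RHS19 (AT5G67400) (-0.63, adjusted p = 0.000225) fell. In the iron list ABCG37 (AT3G53480), an exporter of coumarins, rose (0.26, adjusted p = 0.00446) and FRU (AT2G28160), the regulator of iron uptake, fell (-0.48, adjusted p = 0.00806). The other 16 of 18 were not called (2 higher and 3 lower adjusted over the list alone, adjusted p = 0.00967, and adjusted p = 0.421 with an estimated correlation). In the ethylene list ERF5 (AT5G47230) rose (0.49, adjusted p = 0.000253) and AT2G19590, an ACC oxidase gene, fell (-0.44, adjusted p = 0.00698), of 14 tested (2 and 3 adjusted over the list alone). In the clock list PCL1 (AT3G46640) (0.34) and PRR5 (AT5G24470) (0.31) rose and PRR9 (AT2G46790) fell (-0.39), of 12 tested (3 and 2 adjusted over the list alone). The calls of PCL1, PRR9 and PRR5 were lost in 3, 4 and 5 of the 6 fits without a library. The highest adjusted p came without mock replicate 1 for PCL1 and PRR9 (0.0579 and 0.0886) and without rapamycin replicate 2 for PRR5 (0.123). Of 11 brassinosteroid genes 2 fell, BEE1 (AT1G18400) (-0.59) and ROT3 (AT4G36380) (-0.26), with 2 higher and 3 lower adjusted over the list alone. BEE1 lost its call in 5 of the 6 fits without a library (highest adjusted p 0.102, without mock replicate 1). ROT3 lost it in 4 (highest 0.134, without mock replicate 4).

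Photosynthesis genes, included as markers of green shoot tissue, had 1 of 16 members lower (1 adjusted over the list alone, adjusted p = 0.0139, and adjusted p = 0.675 with an estimated correlation). The lateral root and jasmonate lists each had 1 member higher (of 18 and 13), and the list of expansins and xyloglucan endotransglucosylases 1 lower (of 15). Adjusted over the list alone these lists had 2 higher and 1 lower, 1 higher and 0 lower, and 2 higher and 1 lower. No member was called in the lists of RGF peptides and RGI receptors (14 tested), stem cell niche (14), S phase (11), G2 and mitosis (17) and heat shock (4), and adjusted over the list alone only the heat shock list had 1, a lower one. The camera adjusted p of these lists ran from 0.0926 to 0.986 over the 8 lists. Across the 9 comparisons within a set, camera with the preset correlation gave 53 list calls, and with an estimated correlation 0. Fry, which does not compare a list with other genes, gave 21, of which camera with the preset correlation also called 14. In the RGI1 line response fry called immunity (higher, adjusted p = 0.0013), suberin (higher, 0.0304) and hypoxia (lower, 0.0304), and in its difference from wild type immunity (0.0146) and suberin (0.0211), both higher. The RGI1 line under mock had 11, the RGI5 line response 3 and the RGI5 line under mock 2, the other comparisons 0.

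**Figure D3:**
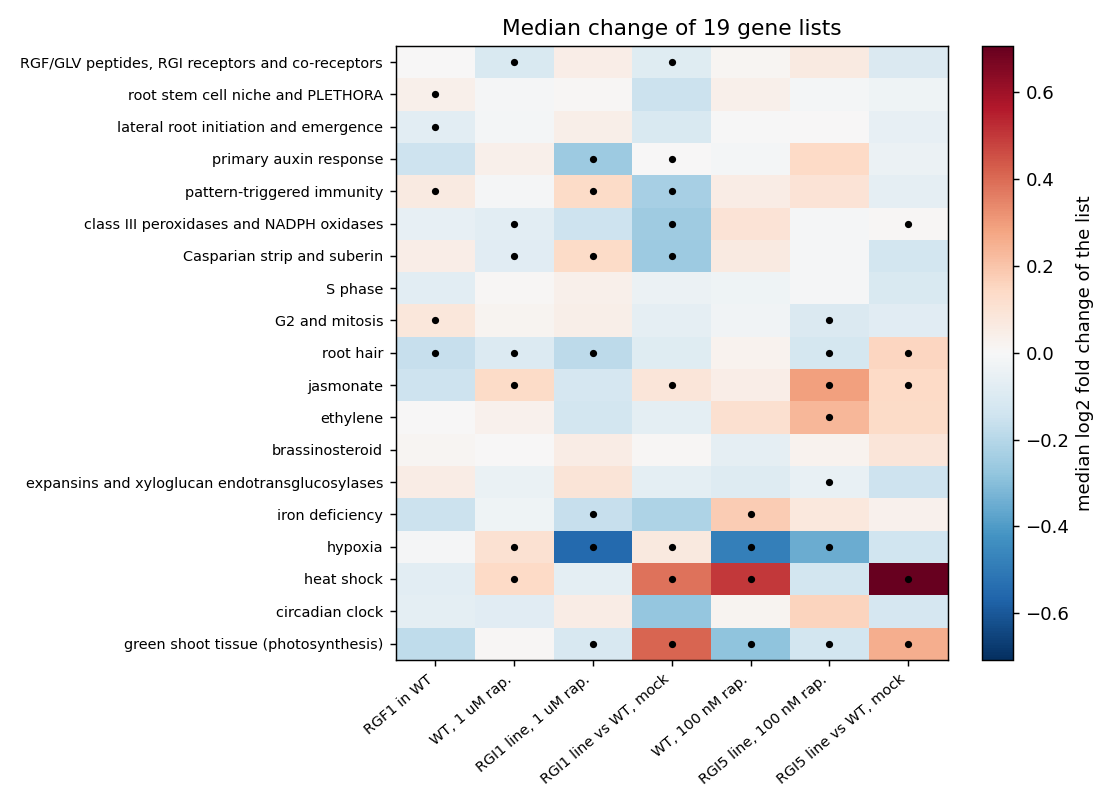
Median log2 fold change (colour) of each of the 19 gene lists (y axis) in 7 comparisons within a set (x axis). Dots mark lists called by camera with the preset correlation, none of which was called with an estimated correlation.

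The response of the RGI1 line was set against that of its wild type in the same fit. The difference was 2.07 for IGMT2 (SE 0.18, adjusted p = 0.000825), 1.96 for GSTF6 (SE 0.18, adjusted p = 0.000825), 1.62 for GSTF7 (adjusted p = 0.000825) and 1.55 for CYP71A12 (SE 0.27, adjusted p = 0.0146). Wild type went from 9.02 to 5.91 TPM for IGMT2, from 260.5 to 217.3 TPM for GSTF6 and from 329.9 to 313.1 TPM for GSTF7. The line under mock stood below wild type under mock for these genes, at 3.21, 107.4 and 148.3 TPM. The peroxidase genes PRX62 (AT5G39580) (1.29, adjusted p = 0.00684) and PRX71 (AT5G64120) (1.19, adjusted p = 0.00544) also had higher changes in the line, their means having fallen in wild type. Other genes of the peroxidase list had lower changes, among them PRX1 (-0.62, adjusted p = 0.00331) and RHS19 (-0.58, adjusted p = 0.00956). XTH26 (-1.65, SE 0.20, adjusted p = 0.002), AT2G36690 (-1.61, adjusted p = 0.000825) and the sulfate transporter gene SULTR1;1 (AT4G08620) (-1.08, SE 0.11, adjusted p = 0.000825) had lower changes in the line: XTH26 went from 56.1 to 18.9 TPM in the line and from 25.8 to 27.9 TPM in wild type, and SULTR1;1 from 9.8 to 3.9 and from 9.68 to 9.23 TPM. Of the 503 genes that rose in the line 150 were called in this difference, and of the 293 that fell 77; the difference holds the same line libraries, so their signs are not independent of the line response. Of the 25 called genes named by the rule, 17 kept their call without each library and 4 also under all other alternatives, CYP71A12 having an adjusted p of 0.734, XTH26 of 0.206, PRX71 of 0.112, PRX62 of 0.0986 and GSTF7 of 0.0531 in the fit of all 30 libraries. The immunity list had 2 of 29 members higher (6 adjusted over the list alone, adjusted p = 0.00129) and the suberin list 1 of 26 (6 adjusted over the list alone, adjusted p = 7.92e-06), both with an adjusted p = 0.123 with an estimated correlation. The hypoxia list had 1 of 11 lower (7 adjusted over the list alone, adjusted p = 1.04e-09, and adjusted p = 0.123 with an estimated correlation). The root hair list was not called in this difference (median -0.06, 1 of 14 members higher and 1 lower, 3 and 4 adjusted over the list alone, camera adjusted p = 0.0699). limma called 245 genes (161 higher, 84 lower), with 2308 at an unadjusted p under 0.05. The split was 119 and 107 after median-ratio scaling and 121 and 111 after quantile normalization, and the fit of all 30 libraries gave 28 calls. Leaving out wild-type mock replicate 1, wild-type rapamycin replicate 2, line mock replicate 3, line mock replicate 4 or line rapamycin replicate 2 gave 125, 156, 116, 128 and 158 calls.

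In the RGI5 line, given 100 nM rapamycin, no gene passed the test. PUCHI differed by 0.03 (SE 0.17, adjusted p = 0.957), LBD16 by 0.00 (SE 0.08, adjusted p = 0.991), LBD29 by 0.12 (SE 0.17, adjusted p = 0.824), LBD18 by -0.01 and GATA23 by 0.00. PLT1 differed by -0.08 (adjusted p = 0.828), PLT2 by -0.02 and RITF1 by 0.22 (adjusted p = 0.562). The ethylene list stood higher, with 14 of 15 members above mock (median 0.23) and 0 called in limma (6 higher adjusted over the list alone, camera adjusted p = 0.00675, and adjusted p = 0.33 with an estimated correlation). Of all genes tested 69% stood above mock (median 0.06). The hypoxia list (median -0.35, adjusted p = 3.68e-05) and the G2 and mitosis list (median -0.10, adjusted p = 3.68e-05) stood lower, both with 0 called, 0 adjusted over the list alone, and an adjusted p = 0.33 with an estimated correlation. As given above, the hypoxia list had a lower median still in wild type with 100 nM rapamycin, so its fall was not particular to the line. limma called 0 of 19652 genes (smallest adjusted p 0.163), while 2174 had an unadjusted p under 0.05. The difference between the responses of the RGI5 line and its wild type also had 0 calls (smallest adjusted p 0.112), with 2130 at an unadjusted p under 0.05. The fit of all 30 libraries gave 75 calls in the line (66 higher, 9 lower) and 127 in the difference, and the difference had 48 calls without wild-type mock replicate 4 and 1 without line mock replicate 1. On simulated data of this design 70.1% of genes with a log2 change of 0.5 and 97.0% of those with a change of 1 were recovered. Those genes had a mean of about 5 TPM or more and were changed together with larger ones, so recovery in the real data may be lower. The share of AT1G15405 was 9.21% ± 0.613 in mock and 6.23% ± 0.371 with rapamycin, without overlap between the groups, and the share of chloroplast-encoded transcripts 5.28% ± 0.171 and 6.41% ± 0.253.

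**Figure D4:**
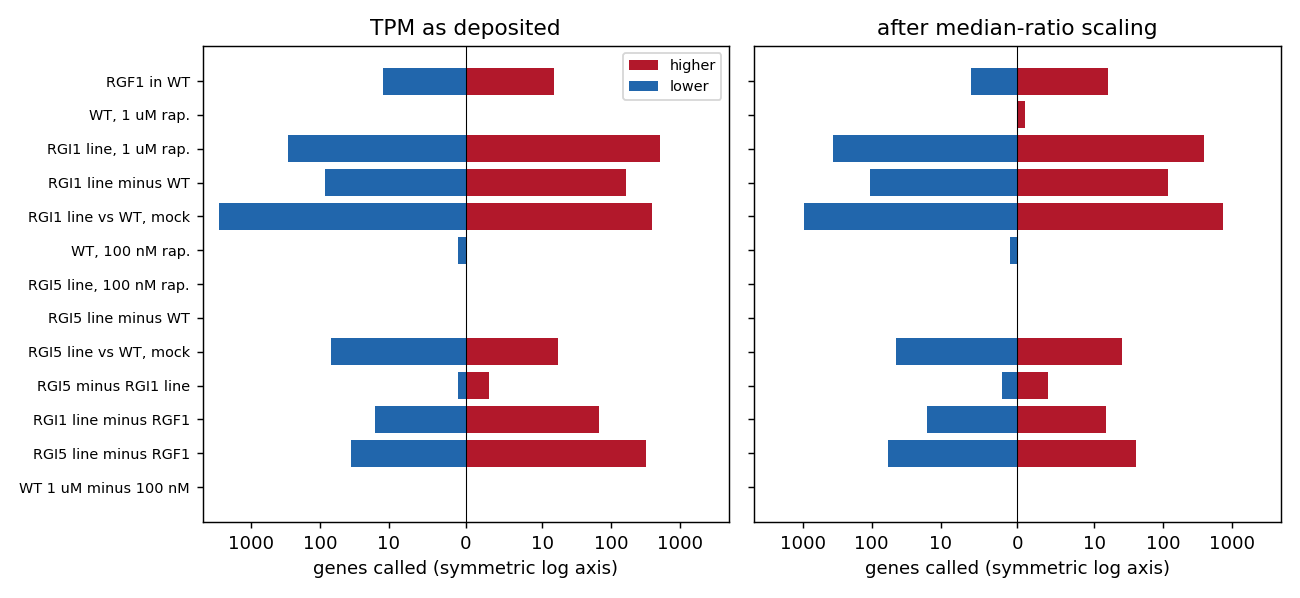
Number of genes called higher (red) and lower (blue) by limma at an adjusted p under 0.05 in each of the 13 comparisons (x axis, symmetric log scale), with TPM as deposited (left) and after median-ratio scaling (right).

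Both lines were compared with their own wild type under mock treatment, which asked how far the lines differed before rapamycin. In the RGI1 line, genes of defence stood lower: the lipase gene PLA2A (AT2G26560) at 1.56 ± 0.261 against 8.01 ± 1.46 TPM (-1.81, SE 0.17, adjusted p = 4.34e-05), the peroxidase gene PER4 (AT1G14540) (-1.44, SE 0.12, adjusted p = 1.85e-05), CYP81F2 (-1.17, SE 0.11, adjusted p = 6.44e-05), CYP71A12 (-1.15, adjusted p = 0.00215), FRK1 (AT2G19190), a flagellin-induced kinase gene (-0.82, adjusted p = 0.00229), and WRKY11 (AT4G31550) (-0.50, adjusted p = 0.000363). The protease gene AT5G48430 (-2.06, adjusted p = 1.35e-05), AT1G33840 (-2.07, adjusted p = 0.000215) and the extensin-like gene AT1G26250 (-1.73, adjusted p = 0.000105) were also lower. Higher in the line were the storage protein genes VSP2 (AT5G24770) at 24.9 ± 3.46 against 8.04 ± 2.11 TPM (1.54, SE 0.23, adjusted p = 0.00122) and VSP1 (AT5G24780) (0.97, adjusted p = 0.000772), which respond to jasmonate, and the photosynthesis genes RBCS1A (AT1G67090) at 18.0 ± 1.14 against 8.22 ± 0.547 TPM (1.04, SE 0.12, adjusted p = 0.000147) and CAB1 (AT1G29930) (1.23, adjusted p = 0.00418). The non-coding RNA AT2G01422 (2.08, SE 0.11, adjusted p = 5.66e-07) and the starch-related gene QQS (AT3G30720) (1.5, SE 0.27, adjusted p = 0.00372) were higher as well. AT5G52355 was listed at 0 in the 3 mock libraries of the line and at 3.35, 5.2 and 5.01 TPM in wild type.

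By list, 13 of 29 immunity genes were lower in the RGI1 line (15 adjusted over the list alone, adjusted p = 0.00211, and adjusted p = 0.12 with an estimated correlation), as were 11 of 19 peroxidase and NADPH oxidase genes, with 1 higher (11 lower and 2 higher adjusted over the list alone, adjusted p = 0.0301, and adjusted p = 0.547 with an estimated correlation). Examples were PRX62 (-1.12), PRX71 (-0.94) and RBOHA (AT5G07390) (-0.53, adjusted p = 0.000273). Of 26 suberin genes 9 were lower (14 adjusted over the list alone, adjusted p = 0.00211, and adjusted p = 0.336 with an estimated correlation), including GPAT5 (AT3G11430) (-0.42, adjusted p = 0.00334). After median-ratio scaling these lists had 11, 7 and 4 members lower. All 4 called jasmonate genes of 13 were higher (5 adjusted over the list alone, adjusted p = 3.51e-06, and adjusted p = 0.0574 with an estimated correlation), as were 2 of 4 heat shock genes, HSP70 (AT3G12580) (0.55, adjusted p = 0.0005) and HSP90.1 (AT5G52640) (0.39, adjusted p = 0.00323), with 2 adjusted over the list alone, adjusted p = 3.51e-06, and adjusted p = 0.0522 with an estimated correlation. Photosynthesis genes, the markers of green shoot tissue, had 8 of 16 members higher and none lower (9 adjusted over the list alone, adjusted p = 8.77e-14, and adjusted p = 0.12 with an estimated correlation), a difference that lay beside those of the immunity, suberin and jasmonate lists in the same libraries. limma called 3239 genes, 393 higher and 2846 lower (6341 at an unadjusted p under 0.05). The split was 729 and 964 after median-ratio scaling and 772 and 1024 after quantile normalization. Without wild-type mock replicate 1 or 2 the count was 1651 or 1587, and without line mock replicate 1 or 3 it was 1686 or 1559. Of the called genes named by the rule, 68 in number, 41 kept their call without each library and 32 under the alternatives as well. Here too the log2 fold change of 1 was not among the alternatives, and a gene that they did not test counted as kept. In the fit of all 30 libraries CYP71A12 and HSP90.1 (both adjusted p = 0.206), AT5G52355 (0.0859) and CYP81F2 (0.0521) were not called. The share of AT1G15405 was 10.9% ± 0.279 in the line and 7.00% ± 0.694 in wild type.

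In the RGI5 line the same comparison had 86 calls, 17 higher and 69 lower (2740 at an unadjusted p under 0.05). QQS stood at 0.589 ± 0.531 TPM against 16.4 ± 3.06 TPM in wild type (-3.48, SE 0.31, adjusted p = 0.000381), and AT2G01422 at 0.390 ± 0.345 against 9.71 ± 2.92 TPM (-2.93, SE 0.30, adjusted p = 0.00148). AT1G27565 was at 0, 0.26 and 0.22 TPM in the line and at 9.28, 9.90 and 8.94 TPM in wild type, and AT3G58347 was listed at 0 in the line and at 1.72, 4.1 and 3.2 TPM in wild type. AT3G58347 was also listed at 0 in wild type with 100 nM rapamycin, so both of its calls rest on the same wild-type mock libraries. Heat shock genes were higher: HSP90.1 at 23.3 ± 4.19 against 10.2 ± 0.98 TPM (1.1, SE 0.18, adjusted p = 0.0277), HSP70 (0.94, adjusted p = 0.0377) and MBF1C (AT3G24500), a regulator of heat tolerance (0.96, adjusted p = 0.0231). Of 4 listed heat shock genes 2 were higher (3 adjusted over the list alone, adjusted p = 0.00025, and adjusted p = 0.0938 with an estimated correlation). Photosynthesis genes stood higher in 15 of 16 cases (median 0.26) with 0 called in limma, 0 adjusted over the list alone, a camera adjusted p of 0.00025 and an adjusted p = 0.527 with an estimated correlation. SADHU3-2 (AT3G42658) (1.61, adjusted p = 0.0201) and MRD1 (AT1G53480) (1.55, adjusted p = 0.0271) were higher, while ASN1 (AT3G47340), an asparagine synthetase gene (-1.59, adjusted p = 0.0277), and GSTF14 (AT1G49860) (-1.62, adjusted p = 0.0447) were lower. The split was 25 and 44 after median-ratio scaling and 24 and 53 after quantile normalization, and the fit of all 30 libraries had 628 calls. Leaving out wild-type mock replicate 2 or 3 gave 29 and 9 calls, and leaving out line mock replicate 1, 2 or 4 gave 7, 8 and 181. HSP90.1, HSP70 and GSTF14 lost their calls in 5 of the 6 fits without a library, SADHU3-2, MRD1 and ASN1 in 4, and MBF1C in 3. For HSP90.1, HSP70, SADHU3-2, MRD1, ASN1 and GSTF14 the highest adjusted p came without wild-type mock replicate 3 (0.123, 0.182, 0.106, 0.106, 0.131 and 0.183). For MBF1C it came without line mock replicate 1 (0.0959).

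Differences between the responses themselves were tested in a fit of all 30 libraries, with the caution that the sets differed in line, receptor, dose and wild-type controls at once. PUCHI rose with RGF1 in wild type and not with rapamycin in the RGI1 line, where its change was lower (-1.46, SE 0.22, adjusted p = 0.00214), nor in the RGI5 line (-1.28, SE 0.22, adjusted p = 0.00605). WRKY30 did likewise (-1.70, adjusted p = 0.0036, and -1.83, adjusted p = 0.0019). In mock and rapamycin libraries of the RGI1 line PUCHI stood at 0.77 and 0.60 TPM and WRKY30 at 0.13 and 0.16 TPM. Such levels are near the floor, so these differences rest mostly on the change with RGF1. In the RGI5 line the chitinase gene AT2G43620 (-1.56, SE 0.21, adjusted p = 0.0019) and the pectin methylesterase inhibitor-like gene AT3G47380 (-2.06, SE 0.29, adjusted p = 0.0019) had lower changes than with RGF1. EXPA12 had a higher change (1.64, SE 0.28, adjusted p = 0.00742), since it fell with RGF1 and stood at 2.30 and 2.35 TPM in mock and rapamycin libraries of the RGI5 line. ELF4-L3 (AT2G06255) (1.33, adjusted p = 0.0021) and the auxin regulator IAA28 (AT5G25890) (0.59, SE 0.10, adjusted p = 0.00804) had higher changes in the line as well. In the RGI1 line AT4G01870 (0.95, SE 0.14, adjusted p = 0.00214) and the dioxygenase gene DOX1 (AT3G01420) (1.02, adjusted p = 0.021) had higher changes than with RGF1. AT4G20450, a receptor kinase gene, had a lower change (-1.12, adjusted p = 0.00341), from 4.84 to 2.06 TPM in the line and from 2.02 to 2.46 TPM with RGF1. DOX1 lost its call in 6 of the 12 fits without a library (highest adjusted p 0.084, without line rapamycin replicate 2). Between both lines, SULTR1;1 differed by 0.89 (RGI5 line minus RGI1 line, SE 0.13, adjusted p = 0.00493), NSP3 (AT3G16390), a nitrile specifier gene, by 1.16 (adjusted p = 0.0237, and 0.0851 without RGI1 line mock replicate 1), and AT4G16660 by 0.50 (adjusted p = 0.015, and 0.0646 without RGI1 line mock replicate 4). NSP3 lost its call in 5 of the 12 fits without a library, and AT4G16660 in 3. AT1G76728 was listed at 0 in all 6 libraries of the RGI5 line and rose in the RGI1 line, as given above.

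limma called 82 genes between the RGI1 line and RGF1 responses (66 higher, 16 lower; 15 and 16 after median-ratio scaling, 16 and 20 after quantile normalization; 2518 at an unadjusted p under 0.05). It called 352 between the RGI5 line and RGF1 responses (316 higher, 36 lower; 41 and 58 after median-ratio scaling, 38 and 59 after quantile normalization; 3898 at an unadjusted p under 0.05). In the latter the median of all genes was 0.11, and median-ratio scaling moved it by -0.11. Between both lines it called 4 (3 higher, 1 lower; 4 and 2 after median-ratio scaling, 11 and 8 after quantile normalization; 1806 at an unadjusted p under 0.05). The count of 82 became 34, 21 and 156 without wild-type mock replicate 1, 2 or 3 of the RGF1 set, 13 without RGF1 replicate 3, 18 and 24 without RGI1 line mock replicate 3 or 4, and 17 and 32 without its rapamycin replicate 2 or 3. The count of 352 became 134, 70 and 869 without wild-type mock replicate 1, 2 or 3 of the RGF1 set, 45 without RGF1 replicate 3, 78 without RGI5 line mock replicate 2 and 135 without its rapamycin replicate 3. The count of 4 became 2 without RGI1 line rapamycin replicate 1, 12 and 17 without RGI5 line mock replicate 1 or 4, and 7, 9 and 20 without its rapamycin replicate 1, 2 or 3.

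The overlap between the peptide and the RGI1 line was small. Of 12 genes called higher with RGF1 and 495 called higher in the RGI1 line, among 19169 tested in both, 3 were shared, where independent lists would share 0.31 (one-sided Fisher's exact test, p = 0.00316). They were AT2G43620, AT1G78850 and AT1G25275, the last 2 named after their values were seen. Of 12 and 284 genes called lower, 0 were shared (0.178 by chance). In the fit of all 30 libraries 6 of 46 and 220 higher genes were shared (0.503 by chance, one-sided Fisher's exact test, p = 1.04e-05) and 5 of 121 and 142 lower genes (0.854 by chance, p = 0.00169). The 3 shared genes became 1, 0, 1 and 0 without wild-type mock replicate 1 and RGF1 replicate 2, 3 or 4. The libraries of both sets are separate, so no controls were shared. In the fit of all 30 libraries, however, the comparisons share an estimate of spread for each gene. The chance values and Fisher's exact tests from that fit do not allow for this. The RGI5 line had no call in the fit of its set and so no overlap to test there. In the fit of all 30 libraries its 66 higher genes shared 7 with the 220 of the RGI1 line (0.722 by chance, one-sided Fisher's exact test, p = 7.67e-06) and its 9 lower genes 1 with the 142 (0.064 by chance, p = 0.0618). With RGF1 they shared 0 higher and 0 lower genes, and 2 genes were called in both in opposite directions.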

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

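Tests on scaling of calls in the RGI1 line under mock, shared calls included, were chosen only after the result was seen. So were those on spread in the RGI5 line and on AT2G01422 and QQS. The others were chosen before. Tests of a difference between responses called 245 genes between the RGI1 line and its wild type, 4 between both lines, 82 between the RGI1 line and RGF1, and 352 between the RGI5 line and RGF1. Both lines differed from their wild type in opposite directions for AT2G01422 (a difference of 5.01 on the log2 scale, SE 0.38, limma adjusted p = 9.07e-09) and for QQS (4.98, SE 0.45, adjusted p = 1.58e-07). For QQS the direction depends on the wild type used, which under mock stood at 2.15 TPM in the RGI1 set and 16.4 TPM in the RGI5 set, with the RGI1 line at 7.81 TPM between them. Splits of the same libraries, the real grouping included, gave as many calls in 1 of 100 for the 245 (highest other 230), 4 of 100 for the 82 (384), 2 of 100 for the 352 (379) and 9 of 100 for the 4 (498). The splits with 498 and 384 calls exchange all labels of the RGI1 line or of the RGF1 set, the first also moving 1 pair of RGI5 libraries, and so add the responses where the real grouping subtracts them, a structure of the samples that follows from the design. That with 379 calls exchanges only 1 pair of RGF1-set libraries, and is not accounted for in this way. The differences with 0 calls, between the RGI5 line and its wild type and between both wild types, have as many in 100 of 100 splits by construction, which carries no information (highest 4 for each). For 3 against 3 the 10 splits are too few for a share under 0.05: as many calls came in 1 split, the real grouping, for RGF1 (27, highest other 4), the RGI1 line (796, 1), the RGI1 line under mock (3239, 2) and the RGI5 line under mock (86, 1), in 2 splits for wild type with 100 nM rapamycin (1, 1), and, by construction at a count of 0, in 10 for wild type with 1 µM (0, 0) and the RGI5 line (0, 2).

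Of 503 genes that rose with rapamycin in the RGI1 line, 262 were lower in that line than in wild type under mock, where independent lists would share 72.9. Scaling as the whole cause is argued against, since after median-ratio scaling 144 of 391 were, where 19.2 would be shared, and the ratio stayed at 7.75 or more without each library in turn. Their median relative to all genes (-0.152 after that scaling) was not used for this, because a factor per library hardly moves it. For genes chosen without them, medians in held-out mock libraries ran from -0.403 to -0.086. None (0 of 9 combinations) lay within 0.05 of all genes, the range that noise needs. This argues against noise of single mock libraries as the whole cause, though the 9 combinations reuse the same 3 mock libraries. A deviation shared by all mock libraries of the line would give the same medians, so this check cannot exclude it. The test set beforehand did not settle the part of noise, since 8 of 9 were past the bound of -0.1 that all had to pass. Simulated libraries without any response gave a covariance of -0.00996 between both comparisons, against -0.0124 observed. That covariance is over all genes, so a part played by noise in these genes stays open. That the line held these genes low before rapamycin, which then raised them, may be a biological explanation: they came nearer wild type in 6 of the 9 combinations and stood 0.15 to 0.231 above wild type after rapamycin in all 9, so this remains open.

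Under mock the RGI1 line had 2846 lower and 393 higher calls. After median-ratio scaling 56.9% of calls were lower, but this scaling centres the median change, which evens the split whatever the cause, so whether scaling of TPM produced the excess stays open. Scaling as the cause of all the calls is argued against, since 1355 of the 3239 genes were also among the 1693 called after it. The line and its wild type differ in transgene and plant material together, so what caused the remaining calls stays open.

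The RGI1 line had 796 calls with rapamycin and the RGI5 line 0. The spread between libraries was larger in the RGI5 set, with a median residual SD of 0.1353 (log2) against 0.1003 in the RGI1 set. At a simulated log2 change of 0.5, 70.1% of changed genes were recovered for the RGI5 line and 88.1% for the RGI1 line. In the fit of all 30 libraries, which pools the spread, the RGI1 line had 362 calls and the RGI5 line 75. Whether this spread hid an equal response was not settled. Genes chosen in the RGI1 line had medians of 0.29 to 0.63 in held-out RGI1 libraries and of 0.11 to 0.15 in the RGI5 line. The latter lay under 0.5 of the former in 9 of 9 combinations, so an equal response was not seen, but single pairs of RGI5 libraries ran from -0.288 to 0.45, too wide to exclude it. Dose, receptor level and line cannot be told apart, with 1 dose of rapamycin tested per line. A direct test of the difference called 4 genes, so most of the gap in counts was not shown to be a difference between the lines.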

How the results depend on the processing

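The engineered receptor check stayed near its value of 2.65, at 2.51 to 2.76 over all alternatives and 2.61 to 2.67 without each library, and no named gene reversed. Of the 53 list calls 0 remained with an estimated correlation, 36 without a filter and 42 to 53 under quantile normalization, median-ratio scaling, the block, a mean of 5 TPM and other pseudocounts. TPM keep no depth, so the precision of weakly expressed genes could not be separated from biological spread. The DESeq2 Wald test, DESeq2 size factors and limma-voom need counts and were not run. Where the cause is not given below, the cause was not tested. Quantile normalization gave 17 calls for RGF1, 1 for wild type with 1 µM rapamycin, 1796 for the RGI1 line under mock, and 19, 36 and 97 for RGI5 line minus RGI1 line, RGI1 line minus RGF1 and RGI5 line minus RGF1. Median-ratio scaling, chosen after seeing the data, gave 1 for wild type with 1 µM, 1693 for the RGI1 line under mock, and 6, 31 and 99 for those 3 differences. Without a filter there were 6 calls for RGF1, 150 for RGI1 line minus wild type, 6 for the RGI5 line under mock, 10 for RGI5 line minus RGI1 line, and an overlap of 0. A mean of 5 TPM and a pseudocount of 0.1 each gave 0 for wild type with 100 nM rapamycin and 12 for RGI5 line minus RGI1 line, and a pseudocount of 5 gave 0 for the former. Requiring a log2 fold change of 1, which removes calls by construction, left 10 for RGF1, 35 for the RGI1 line, 31 for its difference from wild type, 85 and 21 for the RGI1 and RGI5 lines under mock, 2, 11 and 27 for the 3 differences, and an overlap of 0. All 30 libraries in a single fit, which pools the spread of the sets, gave 167 for RGF1, 1 and 0 for wild type with 1 µM and 100 nM, 362 and 28 for the RGI1 line and its difference from wild type, 75 and 127 for the RGI5 line and its difference, 628 for the RGI5 line under mock, and an overlap of 6. Same-numbered replicates showed no clear pairing (0 of 15 pairs had r over 0.1, range -0.065 to 0.08, against -0.173 to 0.127 for other pairs). With values centred within groups of 3, this check cannot exclude a shared batch. The replicate block, which spends degrees of freedom, gave 6 for RGF1, 431 and 55 for the RGI1 line and its difference, 15 for the RGI5 line under mock, 7, 38 and 225 for the 3 differences, 1 between both wild types, and an overlap of 0. Without each library in turn the counts ran from 0 to 23 for RGF1, 0 to 1 for wild type with 1 µM, 402 to 695 for the RGI1 line, 116 to 258 for its difference, 1559 to 2826 under mock, 0 to 3 for wild type with 100 nM, 0 to 0 for the RGI5 line, 0 to 48 for its difference, 7 to 181 under mock, 2 to 20, 13 to 156 and 45 to 869 for the 3 differences, 0 to 1 between both wild types, and 0 to 4 for the overlap.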

Other observations

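Gene families gave a wider view of the RGI1 line response than single genes. Of 24 tested tau-class glutathione transferases, enzymes of detoxification, 9 rose, where 0.61 were expected (one-sided hypergeometric test, adjusted p = 1.17e-06), and 8 and 7 rose under quantile normalization and median-ratio scaling. Among 52 peroxidase superfamily genes 12 rose (adjusted p = 1.17e-06) and 6 fell (adjusted p = 0.0082). Berberine bridge enzyme-like genes (6 of 16, adjusted p = 0.000241), O-methyltransferases (4 of 9, adjusted p = 0.00397) and WRKY transcription factors (7 of 47, adjusted p = 0.0123) had an excess of higher calls, with the same counts under both scalings. Genes named root hair specific (5 of 9, adjusted p = 3.52e-05) and protein disulfide isomerase-like genes (5 of 12, adjusted p = 0.000107) had an excess of lower calls, again with the same counts. Of 23 XTH genes 5 fell (adjusted p = 0.00198) and 3 rose, the latter 1 under quantile normalization and 2 under median-ratio scaling.

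In the RGI1 line under mock, 23 of 47 WRKY genes were lower and 1 higher (adjusted p = 8.97e-06), against 10 lower and 4 higher under quantile normalization and 10 and 3 under median-ratio scaling. Cytochrome P450 genes had 17 of 135 higher (adjusted p = 7.24e-07) and 17 lower, against 23 and 13 under median-ratio scaling. Genes of families are not independent of each other, since paralogs share reads and regulation.

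The tests of the next hypotheses were chosen only after the result was seen. The 499 genes that rose in the RGI1 line may rise in the RGI5 line as well: their median there was 0.16 against 0.06 for all genes, 84.0% were higher against 69.0% of all genes, and the adjusted p was 0.411 in camera with an estimated correlation and 0.138 in fry. Of the 285 genes that fell 63.2% were lower there, against 31.0% of all genes (adjusted p = 0.16 and 0.599), so this stays open. The 284 genes that fell in the RGI1 line may fall with RGF1: their median was -0.13 against -0.05 for all genes, 83.8% were lower against 65.8% of all genes, and the adjusted p was 0.411 and 0.138. The 495 that rose had a median of 0.01 with RGF1 and 53.1% were higher, against 34.2% of all genes (adjusted p = 0.411 and 0.877), so this too stays open. Across genes, which are not independent replicates, the RGI1 line response had a Pearson r of 0.156 with the RGF1 response (19169 genes) and of 0.116 with the RGI5 line response (19409 genes), and the RGF1 and RGI5 line responses had one of -0.052.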
